A study of Mus musculus with 8 samples.

How the data were processed

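RNA was measured in 8 subcutaneous tumours grown from B16-F10 cells, a pigmented mouse melanoma line, 4 from control cells and 4 from HOIP-KO cells. HOIP is the protein encoded by Rnf31. It is the catalytic subunit of the linear ubiquitin chain assembly complex (LUBAC), which also holds HOIL-1 (Rbck1) and SHARPIN (Sharpin) and acts in NF-kB and cell death signalling. Per the labels' protocols, cells mixed with Matrigel were injected under the skin of NSG mice, which lack T, B and NK cells, and tumours were taken after 2 weeks. Poly(A) RNA was made into strand-specific libraries, per the labels' protocols.

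Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1 were used with the mouse build GRCm38 (mm10); the notes give the tools no role or order. The authors deposited 1 table per library, which per the file headers holds an FPKM value (fragments per kilobase of transcript, scaled to the library's total) for each alternative splicing, transcript start or transcript end event of a set of assembled transcripts. Each deposited FPKM was read as the sum over the transcripts that carry the event. The start sum lay within 5% of the gene value defined below for 83.5% of the genes with a mean of at least 1 FPKM, so this reading did not hold in full for every gene; the Rnf31 start event, for example, was below its exon event in control tumours 1 and 2 and HOIP-KO tumour 3. The program that assembled the transcripts and estimated FPKM is not given in the sources used here. Events at 0 were not listed. No counts were given, the smallest listed value was 1e-06 FPKM in each library, and no steps of whole reads could be used, so the sequencing depth is unknown and no counting error is given.

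The 8 tables held 131052 distinct events, 62502 of them in all 8 libraries. Because an assembled locus could merge neighbouring genes, as it did for Rnf31 and Irf9, events were assigned to genes of GENCODE M21 on the same build. An event went to the gene whose exon boundaries matched its splice sites (117497 events, and 355 more after a tie was settled by the gene named in the table) or, failing that, to the only protein-coding gene it lay in (3288 events). The remaining 9809 unassigned and 103 ambiguous events stayed outside all gene tests. Of the splice-site coordinates, 92.6% matched an annotated exon boundary, and 92.7% of the assigned events went to the gene the tables name. A gene's FPKM was the largest, by its mean over all 8 libraries, of its summed start events (9559 genes), its summed end events (3442 genes) and its highest event (1172 genes). This rule did not use the groups and gives a lower limit of a gene's total. It was chosen after the tables were seen, as were the analysis of splicing events and the events given to no gene.

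An FPKM of exactly 0 can be a failed estimate. Uqcrfs1, a respiratory chain subunit that every cell uses, was listed at 0 in 4 libraries and at 42.1 to 130 FPKM in the others, and 471 of the tested genes were at 0 in at least 1 library. Named genes at 0 in a library are therefore described as listed at 0, with the library values of that group and no fold change of means. Values above 0 also varied widely for some abundant genes. Among control tumours, Gapdh ran from 16.15 to 144 FPKM and Hspa8 from 202 to 1462 FPKM, and neither gene was called.

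The test written before the data were examined was for read counts. For files with FPKM only, the same plan named limma, which was used here (version 3.58.1 under R 4.3.3, with statmod 1.5.0). Empirical Bayes moderation with a mean-variance trend was run on log2(FPKM + 1) for the 10754 genes with at least 1 FPKM in at least 4 libraries, HOIP-KO minus control, with no replicate term. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Counts of genes changed at least 2-fold use this scale. A change of a named gene given as a multiple is the ratio of its mean FPKM in the 2 groups. No scaling beyond FPKM was applied. The labels do not say whether the tumours came from separate mice or cell cultures, so p-values measure only the spread between these samples. Gene values were built with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

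Before the data were examined, 30 gene lists were fixed: pathways linked to LUBAC or to melanoma, markers of other cell types that a tumour can hold, and RNA quality genes. The 21 lists with at least 5 tested genes were compared with all other genes by limma's camera, with a preset correlation between genes of 0.01, and adjusted over the lists. Camera was repeated with the correlation estimated from the data, and fry, limma's rotation test of whether a list moved on balance, was run beside it. Chromosomes were tested as sets in the same way, and medians were taken over windows of 100 or more consecutive tested genes. A further 4 lists were added after values had been seen.

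The rule for the genes named here was also fixed beforehand. It takes Rnf31, Rbck1 and Sharpin; the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap and whose mean was at least 2 FPKM in the higher group, leaving out bare identifiers and clone names; and up to 4 called members per list, or the 2 most abundant members where none was called. It yielded 105 genes, of which some are not reported here. The rule was worded for CPM and was applied to FPKM. Genes named outside it for their values are said to have been chosen after these were seen. Uqcrfs1, Gapdh and Hspa8 above were chosen in that way too.

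For exon skipping and intron retention, the share of FPKM carried by the including form was tested with limma in pairs with at least 1 FPKM over both forms in every library and a mean share of 5% to 95%. A change counted at an adjusted p under 0.05 and 10 or more percentage points.

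The fit was tested on simulated data built on the 10754 genes, with 200 genes changed in each of 60 runs. It called 26.5% of the genes changed by 0.5 on the log2 scale, 73.0% of those changed by 1 and 93.7% of those changed by 2, and 5.2% of the calls were false. Far fewer genes changed in these runs than were called in the real data, so the shares called do not carry over to the real fit. In each run a further list of genes was changed by the same amount. Camera gave an unadjusted p under 0.05 for 100% of these changed lists and for 5% of the unchanged ones. Genes were simulated independently of each other, so these shares do not hold for lists whose genes move together. In the real data the estimated correlation reached 0.52 for oxidative phosphorylation genes and 0.81 for erythroid genes. The number of runs was raised from 20 after the first runs. For event usage, simulated changes were placed only on events with a mean share near the middle of the range. Of these, 0% of changes of 20 percentage points and 24.9% of changes of 40 points were called. The median SD between libraries was 13.1 points over all events. The size of 40 points was added after the smaller size gave no calls.

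Alternatives that were planned were a pseudocount of 0.1, no filter on low FPKM, the replicate number as a block, leaving out each library in turn, and the other set tests. Alternatives chosen after seeing the data were scaling by the median ratio to the geometric mean, each of the 3 kinds of gene value alone, genes with at least 2 of those values within 5%, and leaving out chromosomes 6, 11, 14, 16 and 19. All 35 ways to divide the 8 libraries into 2 groups of 4 were refitted. The planned count tests and count scalings were not run because the tables hold no counts, and tests of annotation terms were not run because the tables hold no such annotation.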

Results

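The series asked how loss of HOIP changes gene expression while B16-F10 melanoma cells form tumours in immunodeficient mice. Gene FPKM were obtained for 8 tumours collected 2 weeks after injection, 4 control and 4 HOIP-KO. Each library listed 10415 to 10790 genes at 1 FPKM or more, with a median of 10.1 to 10.4 FPKM among them. The 20 most abundant genes took 9.19% to 10.6% of the summed FPKM. Sequencing depth is unknown, so the precision of each value is given only by the spread between the 4 tumours of a group. Across genes, log2(FPKM + 1) correlated at 0.968 to 0.971 among control tumours, 0.95 to 0.973 among HOIP-KO tumours and 0.899 to 0.925 between the groups. The first principal component took 52.9% of the variance and separated the groups. The second took 15.6% and set HOIP-KO tumour 2, at −37.8, apart from the other HOIP-KO tumours at 10.0 to 17.1.

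Rnf31, which encodes HOIP, was lower in every HOIP-KO tumour. It was measured at 5.72, 5.66, 4.39 and 5.00 FPKM in control tumours 1 to 4 and at 1.55, 1.32, 2.22 and 0.76 FPKM in HOIP-KO tumours 1 to 4. The log2 fold change was −1.36 ± 0.18 (SE; limma adjusted p = 0.000851, n = 4 per group). The gene (ENSMUSG00000047098) lies on the plus strand of chromosome 14, positions 55591708 to 55603693 of GRCm38, and its value came from an event at 55596007 to 55596255. The labels do not say which part of the gene was targeted, so transcript remaining in HOIP-KO tumours does not measure remaining protein. The other LUBAC subunits did not pass the test. Rbck1 was at 35.5 ± 1.75 FPKM (SD, n = 4) in control and 35.7 ± 4.18 in HOIP-KO tumours, and Sharpin at 22.1 ± 4.86 and 20.9 ± 6.20 FPKM.

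Genes next to Rnf31 also fell. Of 37 other tested genes within 1 Mb, 21 were called lower and 2 higher, with a median log2 fold change of −0.56, and 4 of them fell by more than Rnf31. Psme1 and Psme2, neighbouring genes for subunits of the PA28 proteasome activator, fell by 0.98 and 1.23 on the log2 scale. With end-site sums as gene values, an alternative chosen after seeing the data, Psme2 no longer passed (log2 fold change −0.48, adjusted p = 0.143).

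Of the 10 tested genes of the LUBAC and linear ubiquitin list, 3 rose and Rnf31 fell, with the same counts when adjusted over the list alone. Tnip1, a ubiquitin-binding inhibitor of NF-kB signalling, rose from 26.3 ± 3.25 to 47.2 ± 2.02 FPKM. Otulin, the deubiquitinase specific for linear chains, rose by 0.60 ± 0.16 (log2), and Optn by 0.45 ± 0.09. The Otulin call was lost without control tumour 3 or 4 or HOIP-KO tumour 3 or 4 (adjusted p 0.0551 to 0.0699), and with the highest event alone (0.0732). Optn turned to −0.58, not called, with end-site sums. The list as a whole did not pass camera (adjusted p = 0.194).

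**Figure D1:**
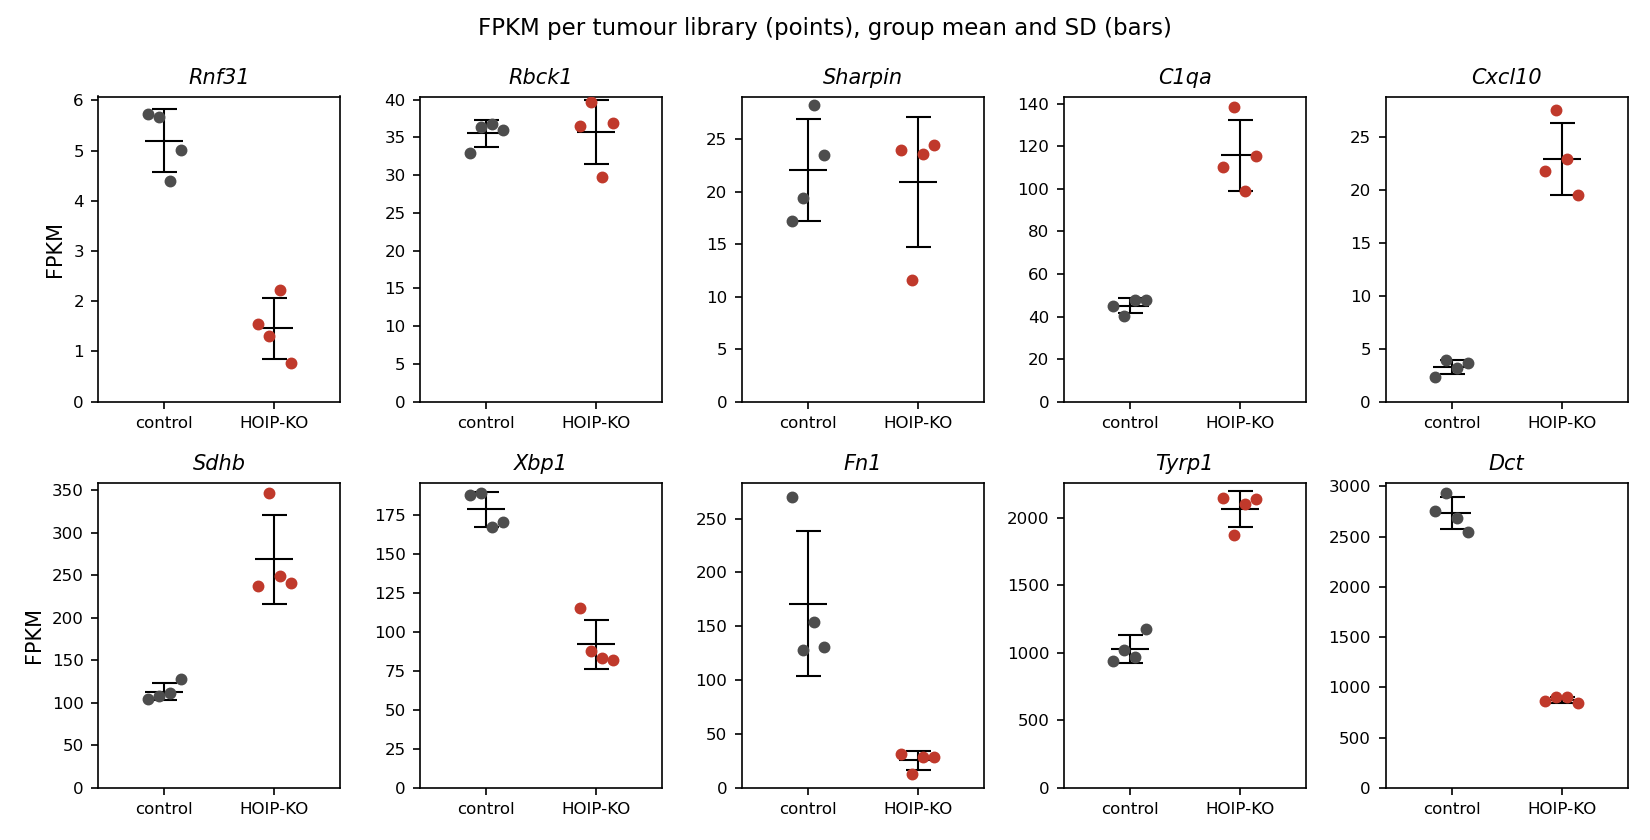
FPKM of 10 genes in each tumour (vertical axis, linear, from 0) by group (horizontal axis). Points are single libraries, the longer line is the group mean and the bars show ±1 SD, n = 4 per group; Rnf31 was 5.20 ± 0.63 in control and 1.46 ± 0.60 FPKM in HOIP-KO tumours, while the groups overlapped for Rbck1 and Sharpin.

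Across the transcriptome, 2718 of 10754 tested genes differed at an adjusted p under 0.05, 1203 higher and 1515 lower in HOIP-KO tumours. With median-ratio scaling, chosen after seeing the data, 1330 were higher and 1379 lower. Of the 2718, 723 changed at least 2-fold, 289 upwards and 434 downwards. The 4 HOIP-KO tumours lay entirely on one side of the 4 control tumours for 3307 tested genes (30.8%), where chance gives 2.86%. The median log2 fold change of all tested genes was −0.05. Among called genes, 14 were listed at 0 in all control tumours and 57 in all HOIP-KO tumours. The labels do not say whether the HOIP-KO cells were 1 clone or a pool, so differences between clones are not separated from the loss of HOIP in any of these changes.

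Several of the largest rises were genes listed at 0, or nearly so, in control tumours. P3h2, a collagen prolyl 3-hydroxylase, was listed at 0 in all 4 control tumours and at 15.3, 9.57, 12.4 and 14.9 FPKM in HOIP-KO tumours 1 to 4. Aqp6, an aquaporin, was listed at 0 in the control tumours and at 9.79, 15.7, 13.6 and 2.66 FPKM, and Cym, which encodes chymosin, at 0 and then 4.80, 7.06, 4.60 and 4.00 FPKM. Glod5 was listed at 0, 0, 0.349 and 0.486 FPKM in control tumours 1 to 4 and at 10.7 to 18.2 in HOIP-KO tumours. B3galt5, a galactosyltransferase, was listed at 0 in 3 control tumours and at 1.49 FPKM in control tumour 3, against 8.58 to 18.4. Trnp1 was listed at 0, 0.225, 0 and 0.051 FPKM in control tumours 1 to 4 and at 4.76 to 13.1 FPKM in HOIP-KO tumours. Gstk1, a glutathione transferase, was listed at 0, 1.37, 0.562 and 0.846 FPKM in control tumours 1 to 4 and at 7.33 to 16.9 FPKM in HOIP-KO tumours. Plscr2, of the phospholipid scramblase family, rose from 1.91 ± 0.54 to 22.9 ± 2.19 FPKM. Etl4 rose by 2.55 ± 0.14, Epb41l3 by 2.63 ± 0.23 and Gsta2, another glutathione transferase, by 2.54 ± 0.45 on the log2 scale. Epb41l3 missed the threshold with start-site sums (log2 fold change 1.81, adjusted p = 0.0942). Slc24a5 (ENSMUSG00000035183; chromosome 2, 125068124 to 125088677), a melanosomal cation exchanger, rose 6.67-fold from 11.6 ± 1.36 to 77.1 ± 3.07 FPKM.

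Among the largest falls, Pgam2, the muscle phosphoglycerate mutase, fell from 53.1 ± 10.1 to 1.19 ± 0.56 FPKM. Arhgef16 was at 28.3, 21.2, 8.37 and 33.5 FPKM in control tumours 1 to 4 and was listed at 0 in all HOIP-KO tumours. Acsbg1, an acyl-CoA synthetase, was at 19.7 to 23.9 FPKM in control tumours and was listed at 0 in HOIP-KO tumours 1 to 3 and at 0.581 in HOIP-KO tumour 4. Col11a1, a chain of cartilage collagen type XI, was at 14.4 to 22.9 FPKM and listed at 0 in all HOIP-KO tumours, and Col9a1, of type IX collagen, fell from 35.7 ± 9.37 to 1.96 ± 0.34 FPKM. The long noncoding RNA Tslrn1 and the homeobox gene Rhox2h were listed at 0 in all HOIP-KO tumours and stood at 11.2 to 16.1 and 9.78 to 14.6 FPKM in control tumours. Xlr3c and Dppa4 ran from 13.9 to 16.5 and from 10.5 to 13.2 FPKM in control tumours. In HOIP-KO tumours 1 to 4, Xlr3c was listed at 0.197, 0, 0.741 and 0.512 FPKM, and Dppa4 at 0 except in tumour 3 (0.515 FPKM). Mgll, monoacylglycerol lipase, fell from 48.0 ± 8.49 to 3.19 ± 0.86 FPKM, Ndufa4l2, a hypoxia-induced mitochondrial protein, from 59.2 ± 17.5 to 4.57 ± 0.51, and Gas7 from 55.5 ± 20.2 to 4.36 ± 1.09. Rhox2h, Xlr3c, Gsta2, Bcl2a1b, H2-Q4, Lyz2, Trim30a and the globins belong to families of similar genes, and their values are uncertain where reads were shared.

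Macrophage genes rose. Of 11 tested markers of macrophages and monocytes, 9 rose and 1 fell (9 and 1 when adjusted over the list alone), with a median log2 fold change of 0.92. The list passed camera (adjusted p = 9.88e-06) but not with an estimated correlation (adjusted p = 0.142). The complement genes C1qa and C1qb, made mainly by macrophages, rose from 45.1 ± 3.61 to 116 ± 16.6 FPKM and from 37.9 ± 1.48 to 100.2 ± 15.3 FPKM. C1qc rose by 1.21 ± 0.14 and Lyz2, lysozyme, by 1.22 ± 0.16 (log2). Cd68, a lysosomal protein named after its value was seen, fell from 97.9 to 62.5 FPKM.

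Among type I interferon response genes, 10 of 28 rose and 0 fell (11 and 0 when adjusted over the list alone). Their median log2 fold change was 0.45, and camera gave an adjusted p of 6.51e-05, or an adjusted p of 0.324 with an estimated correlation. Ddx58, which encodes the RNA sensor RIG-I, rose from 3.95 ± 0.16 to 10.7 ± 1.45 FPKM. Rtp4, Trim30a and Ifi27l2a, all interferon-induced, rose by 1.15 ± 0.14, 1.17 ± 0.17 and 0.86 ± 0.20 (log2). In HOIP-KO tumour 1 the list median stood at 0.19 relative to the control mean, against 0.48 to 0.50 in the other HOIP-KO tumours.

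NF-kB pathway genes and targets rose more often than they fell, 13 against 2 of 30 (the same counts when adjusted over the list alone). The median was 0.23, with a camera adjusted p of 0.000201 and an adjusted p of 0.105 with an estimated correlation. Cxcl10 (ENSMUSG00000034855; chromosome 5, 92346638 to 92348889), a chemokine induced by interferon and NF-kB, rose 7.0-fold from 3.27 ± 0.67 to 22.9 ± 3.38 FPKM. Vcam1, a leukocyte adhesion molecule, rose by 1.37 ± 0.12 from 1.16 FPKM, and Bcl2a1b, an anti-apoptotic Bcl-2 relative, by 1.40 ± 0.15 (log2) from 0.59 FPKM. Macrophage markers rose in the same tumours (median 0.92), and whole-tumour RNA does not show which cells carried the NF-kB changes. Lcn2, lipocalin 2, went the other way, from 1.75 to 2.94 FPKM in control tumours to 0, 0.147, 0.031 and 0.609 FPKM in HOIP-KO tumours 1 to 4.

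Of 21 chemokine and cytokine genes, 5 rose and 2 fell (5 and 2 when adjusted over the list alone). The median was 0.16 and the camera adjusted p 0.0152, or an adjusted p of 0.347 with an estimated correlation. Ccl8, a monocyte-attracting chemokine, rose from 53.8 ± 3.73 to 131 ± 26.8 FPKM and Cxcl16 from 1.66 ± 0.25 to 4.46 ± 0.39. Ccl6 was called at 0.97 ± 0.27, but its call was lost without control tumour 1, 2 or 3 or HOIP-KO tumour 2 or 4 (adjusted p 0.0505 to 0.0729). Without genes on chromosomes 6, 11, 14, 16 and 19 the list no longer passed (adjusted p = 0.527). That removed Ccl8, Cxcl16 and Ccl6, which rose although genes on their chromosome, 11, were lower (median −0.19). The loss therefore does not show that a chromosome shift carried the rise.

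The lists for interferon gamma-inducible genes (3 of 11 rose and 1 fell, adjusted p = 0.172), MHC class I (5 of 17 rose and 2 fell, adjusted p = 0.149) and MHC class II (2 of 8 rose and 1 fell, adjusted p = 0.503) did not pass camera. Adjusted over the list alone, the counts were 3 and 1, 5 and 3, and 2 and 1. Without the 5 chromosomes named above, the first of these lists passed at an adjusted p of 0.0186 and MHC class I at 0.00782, both with the preset correlation. Over all chromosomes each stood at an adjusted p of 0.391 with an estimated correlation. The removal took out Irgm1, on chromosome 11, the only gene of the first list called lower. It also took out Psme1 and Psme2, on chromosome 14, the only MHC class I genes called lower. Both passes therefore came with the loss of these falling genes and do not show a wider rise. B2m, the light chain of MHC class I, rose from 398 ± 11.3 to 854 ± 152 FPKM, and H2-Q4 by 1.63 ± 0.13. Gbp3, an interferon-induced GTPase, rose by 0.71 ± 0.16, and the related Gbp7 was called at 0.48 ± 0.13. Irgm1, another interferon-induced GTPase, fell by 1.36 ± 0.11. Ctss, cathepsin S, rose by 1.14 ± 0.12, while Cd74 (log2 fold change −0.46 ± 0.12) and Ifi30 (0.36 ± 0.11) were called narrowly. The Gbp7 call was lost without control tumour 1 or 2 or HOIP-KO tumour 1, 3 or 4 (adjusted p 0.0603 to 0.0759) and with the replicate block (0.0647), that of Cd74 without control tumour 2 or HOIP-KO tumour 1, 3 or 4 (0.0525 to 0.0566), and that of Ifi30 without any single control tumour or HOIP-KO tumour 3 or 4 (0.0534 to 0.121), with no filter (0.0531) and without the 5 chromosomes (0.0561). In HOIP-KO tumour 2 the MHC class II median stood at 0.38 against −0.09 to −0.07 in the other HOIP-KO tumours.

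Oxidative phosphorylation genes rose together. Of 23 tested, 17 rose and 0 fell (19 and 0 when adjusted over the list alone). The median log2 fold change was 0.71 and the camera adjusted p 1.16e-10, or an adjusted p of 0.324 with an estimated correlation. Atp5o, of ATP synthase, rose from 96.7 ± 12.2 to 283 ± 44.3 FPKM. Sdhb, of respiratory complex II, rose from 113 ± 10.3 to 268 ± 52.2 and Cox5a, of complex IV, from 168 ± 20.1 to 381 ± 125 FPKM, and Atp5g1 rose 2.02-fold. The list median stood at 1.12 in HOIP-KO tumour 2 and at 0.62 to 0.64 in the other HOIP-KO tumours.

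Hypoxia and glycolysis genes moved down, 9 of 22 falling and 0 rising (9 and 0 when adjusted over the list alone). The median was −0.39, the camera adjusted p 0.0131 and the adjusted p with an estimated correlation 0.324; with end-site sums the list missed the threshold (adjusted p = 0.107). Hk2, hexokinase 2, fell from 70.2 ± 3.55 to 34.3 ± 4.87 FPKM, and the collagen prolyl 4-hydroxylase subunits P4ha1 and P4ha2 fell by 0.79 ± 0.10 and 1.52 ± 0.16 (log2). Ankrd37, a target of the hypoxia-inducible factor, fell by 1.11 ± 0.19.

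ER stress and amino acid response genes fell, 12 of 19, with 1 rising (12 and 1 when adjusted over the list alone). The median was −0.51, the camera adjusted p 0.000201 and the adjusted p with an estimated correlation 0.324. Xbp1, a transcription factor of the unfolded protein response, fell from 178 ± 11.4 to 92.0 ± 15.7 FPKM, and the ER protein disulfide isomerase Pdia4 from 197 ± 3.52 to 95.1 ± 3.47 FPKM. Creld2 and Chac1, both induced by ER stress, fell by 1.10 ± 0.14 and 1.19 ± 0.15 (log2). Ddit3, which encodes the stress transcription factor CHOP and was named after its value was seen, rose from 42.9 to 65.5 FPKM.

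The cholesterol and lipid synthesis list did not pass (4 of 21 rose and 2 fell, or 6 and 4 when adjusted over the list alone; camera adjusted p = 0.986), and its median of −0.11 and camera's upward direction differed in sign. Scd1, stearoyl-CoA desaturase, fell by 1.43 ± 0.30, and Srebf1, a regulator of lipid synthesis, by 0.62 ± 0.09, a call lost with start-site sums (adjusted p = 0.141). Hmgcs1 and Idi1, of cholesterol synthesis, were called at 0.45 ± 0.12 and 0.39 ± 0.11. Both of these calls were lost without control tumour 1 or 4 or HOIP-KO tumour 3 or 4, and that of Idi1 also without control tumour 2 (adjusted p 0.0516 to 0.0680). The list median was −0.33 in HOIP-KO tumour 2 and −0.01 to 0.03 in the other HOIP-KO tumours.

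Pigmentation genes changed in both directions. Of 19 tested genes of the melanocyte lineage, 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with a median of 0.36, a camera adjusted p of 0.0131 and an adjusted p of 0.324 with an estimated correlation. With end-site sums the list missed the threshold (adjusted p = 0.0601). Tyrp1, a melanosomal enzyme, rose 2.01-fold from 1028 ± 106 to 2065 ± 130 FPKM. Dct (ENSMUSG00000022129; chromosome 14, 118012790 to 118052244), dopachrome tautomerase, which acts in the same pathway, fell 3.11-fold from 2731 ± 158 to 878 ± 30.0 FPKM. Trpm1, a melanocyte ion channel, rose from 55.6 ± 6.42 to 112 ± 12.8 FPKM, but stood at −0.54 (log2), not called, with end-site sums.

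Cell cycle genes were little changed, with 2 of 29 rising and 0 falling (the same when adjusted over the list alone; camera adjusted p = 0.777). The list's median of −0.09 and camera's upward direction differed in sign. Ccnd1, cyclin D1, rose by 0.51 ± 0.07 and Mcm4, of the replicative helicase, by 0.49 ± 0.09 (log2). Of the death receptor, necroptosis and apoptosis genes, 4 of 25 rose and 1 fell (the same when adjusted over the list alone; camera adjusted p = 0.194). Tnfrsf10b, the mouse TRAIL receptor, fell by 0.53 ± 0.12. Casp4, an inflammatory caspase, was called at 0.75 ± 0.21, but lost its call without control tumour 2 or 3 or HOIP-KO tumour 1 or 3 (adjusted p 0.0613 to 0.0747) and with the highest event alone (0.120). Of 16 p53 targets, 1 rose and 4 fell (the same when adjusted over the list alone; camera adjusted p = 0.707). Gdf15, a stress-induced cytokine, fell from 33.2 ± 4.61 to 12.7 ± 2.32 FPKM and Sesn2 by 0.61 ± 0.08, whereas Sesn1 rose by 0.50 ± 0.11.

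Markers of other cell types did not move as macrophage genes did. Of 16 fibroblast and extracellular matrix genes, 0 rose and 3 fell (0 and 1 when adjusted over the list alone), with a median of −0.47, a camera adjusted p of 0.0152 and an adjusted p of 0.391 with an estimated correlation. Without HOIP-KO tumour 2 the list missed the threshold (adjusted p = 0.0851), as it did with start-site sums (0.0776) and with only the genes whose kinds of value agreed (0.0532). Fn1 (ENSMUSG00000026193; chromosome 1, 71585520 to 71653200), fibronectin, fell 6.68-fold from 171 ± 67.3 to 25.6 ± 8.54 FPKM. Col1a1 and Postn were called at −0.70 ± 0.21 and −0.54 ± 0.17, but Col1a1 lost its call without control tumour 1 or 4 or HOIP-KO tumour 1, 2 or 3 (adjusted p 0.0650 to 0.0864) and with no filter (0.0555), and Postn without any single control tumour or HOIP-KO tumour 1, 2 or 3 (0.0643 to 0.111) and in 5 other alternatives (0.0501 to 0.0793).

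Endothelial genes gave 1 rise and 1 fall among 11 (the same when adjusted over the list alone; camera adjusted p = 0.434). Vwf, von Willebrand factor, rose from 7.47 ± 0.57 to 18.8 ± 3.64 FPKM, and Cdh5, VE-cadherin, was called at −0.33 ± 0.10, a call lost without any control tumour or HOIP-KO tumour 1 or 4 (adjusted p 0.0550 to 0.0854), with the replicate block (0.0781), with median-ratio scaling (0.0533) and with start-site sums (0.0634). Of 6 pericyte and smooth muscle genes, 0 rose and 2 fell (the same when adjusted over the list alone; camera adjusted p = 0.194). These were Acta2, smooth muscle actin (−0.67 ± 0.19), and Notch3, which was at 1.08 to 2.42 FPKM in control tumours and listed at 0.907, 0.552, 0 and 0.92 FPKM in HOIP-KO tumours 1 to 4. Acta2 lost its call without control tumour 1, 3 or 4 or HOIP-KO tumour 1 or 4 (adjusted p 0.0569 to 0.0753) and with the replicate block (0.0631), and Notch3 without control tumour 1, 3 or 4 or HOIP-KO tumour 2 or 3 (0.0711 to 0.117) and in 5 other alternatives (0.0504 to 0.118), the pseudocount of 0.1 among them. Schwann and nerve genes gave 1 rise and 3 falls of 7 (the same when adjusted over the list alone; camera adjusted p = 0.149). Mbp, myelin basic protein, fell from 401 ± 55.3 to 167 ± 41.4 FPKM and the adhesion molecule Ncam1 by 1.28 ± 0.30. Whole-tumour RNA does not show whether nerve or tumour cells carried these transcripts.

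Erythroid genes did not pass, with 0 of 5 called in either direction, or 0 and 4 when adjusted over the list alone (camera adjusted p = 0.0895). Hba-a1 and Hbb-bs, globin genes, were at 95.5 ± 39.2 and 161 ± 59.2 FPKM in control and 45.1 ± 25.4 and 80.4 ± 45.4 FPKM in HOIP-KO tumours. The list median was −0.04 in HOIP-KO tumour 2 against −1.41 to −1.32 in the other HOIP-KO tumours, and without that tumour the list passed as lower (adjusted p = 0.0253), as it did without control tumour 4 (0.0213) and with the replicate number as a block (0.0288), each with the preset correlation. Over all libraries its adjusted p was 0.465 with an estimated correlation. Lists with fewer than 5 tested genes are given as counts. Of 4 adipocyte genes, Adipoq (−0.69 ± 0.21) and Cidec (−0.97 ± 0.26) were called lower and 2 were not called (0 and 3 when adjusted over the list alone). The Adipoq call was lost without control tumour 1, 3 or 4 or HOIP-KO tumour 1, 3 or 4 (adjusted p 0.0502 to 0.0983), with no filter (0.0515), with the replicate block (0.0994) and with start-site sums (0.0536), and that of Cidec without control tumour 1 or HOIP-KO tumour 1 or 3 (0.0559 to 0.0684). Ckm, the only muscle gene tested, fell from 16.5 ± 0.96 to 2.17 ± 1.14 FPKM. Cd79a, a B cell receptor component and the only lymphocyte gene tested, fell from 8.48 ± 1.11 to 4.10 ± 0.55 FPKM. NSG mice lack B cells, so this value does not measure them, and its source was not tested. The dendritic cell genes Batf3 (4.85 ± 0.98 and 4.23 ± 0.86 FPKM) and Zbtb46 (2.51 ± 0.57 and 1.76 ± 0.40) and the epithelial gene Dsp (2.69 ± 0.36 and 2.40 ± 0.51) were not called. No gene of the neutrophil, mast cell or mitochondrially encoded lists was tested. Of 4 nuclear-retained or immediate early genes, Egr1 and Meg3 fell by 1.74 ± 0.25 and 1.09 ± 0.21 (0 and 2 when adjusted over the list alone), the latter call being lost with end-site sums (adjusted p = 0.0535) or the highest event alone (0.341).

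**Figure D2:**
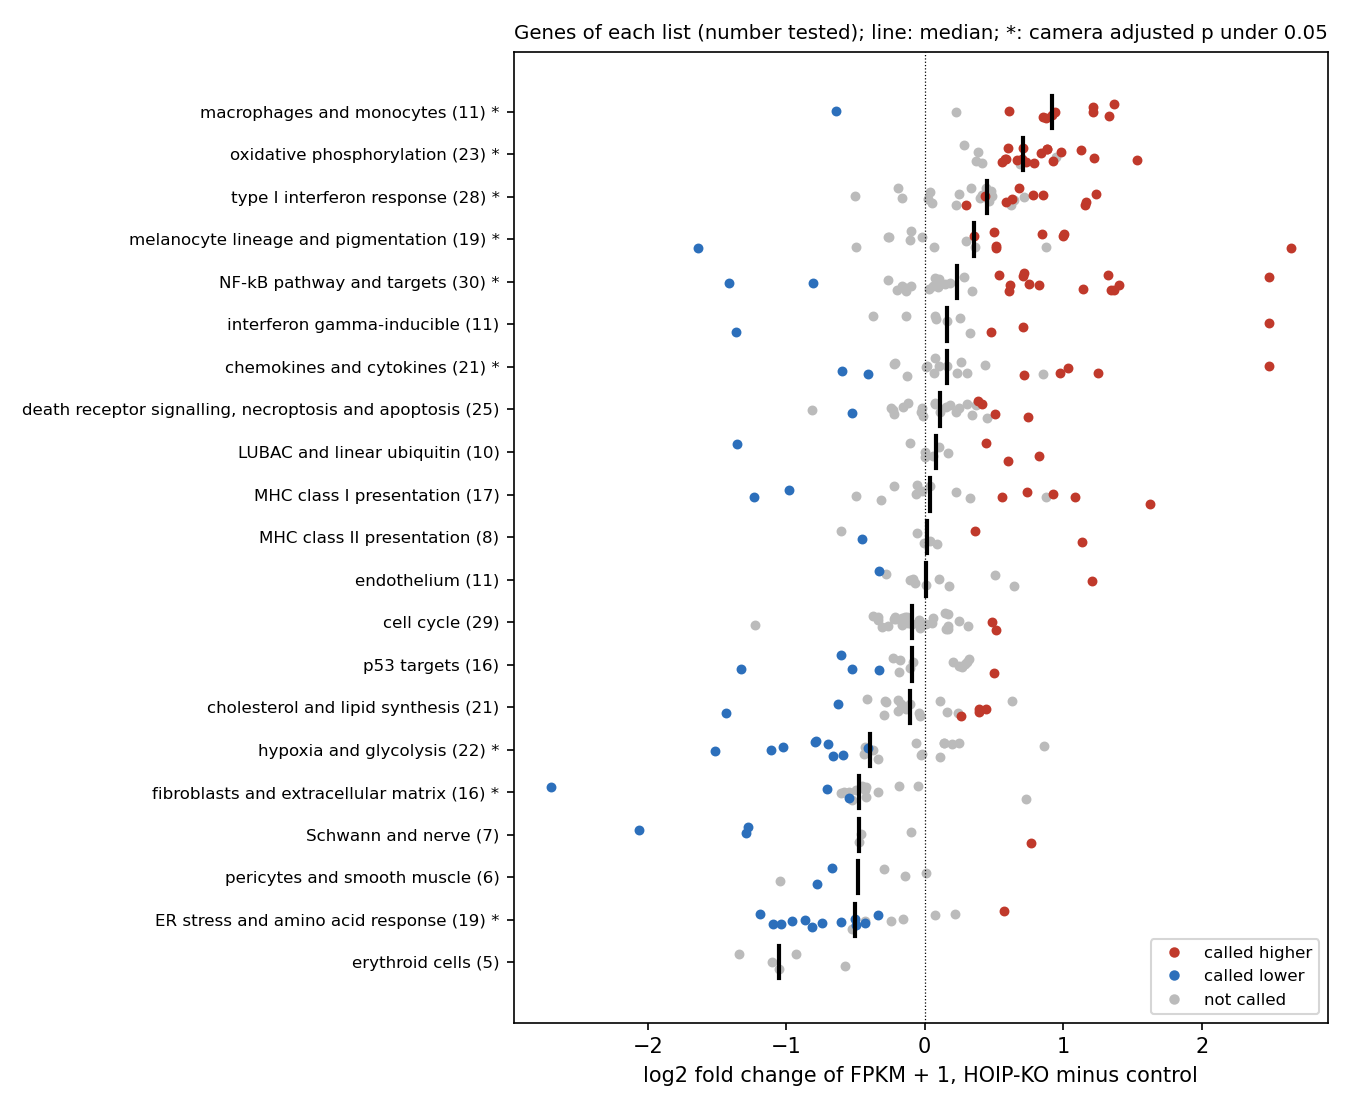
Log2 fold change of FPKM + 1, HOIP-KO minus control (horizontal axis), of every tested gene in the 21 lists tested (vertical axis, number of genes in brackets). Points are genes, coloured by call; black lines are list medians, which run from −1.05 for 5 erythroid genes to 0.92 for 11 macrophage genes, and an asterisk marks an adjusted p under 0.05 by camera with the preset correlation.

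Expression also shifted by chromosome. Genes on chromosome 14 were lower in HOIP-KO tumours (median −0.49, 186 of 375 called lower and 34 higher), as were those on chromosome 6 (−0.36, 222 of 544 lower and 34 higher) and chromosome 11 (−0.19, 226 of 933 lower and 61 higher). Genes on chromosome 16 were higher (0.29, 104 of 336 higher and 11 lower), as were those on chromosome 19 (0.13, 73 of 387 higher and 25 lower). Camera adjusted p-values were 4.31e-08, 1.45e-09, 0.000665, 9.93e-12 and 0.000672 in that order. With an estimated correlation they became 0.00375, 0.00181, 0.0320, 0.00175 and 0.0644, so that chromosome 19 no longer passed, and chromosome 13 did (median 0.00, adjusted p = 0.0320). On chromosomes 6, 11, 16 and 19 every window of at least 100 tested genes was shifted the same way. On chromosome 14 the window medians were −0.27 from 7.8 to 32.2 Mb, −0.03 from 32.2 to 55.6 Mb and −0.68 from 55.6 to 123 Mb, where 116 of 175 genes were called lower. Rnf31 lies at the near edge of this last window and Dct within it. That edge was set by the count of genes per window, and genes called lower lay on both sides of Rnf31. Without the 5 chromosomes, an alternative chosen after these shifts were seen, 1625 genes were called, 842 higher and 783 lower.

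**Figure D3:**
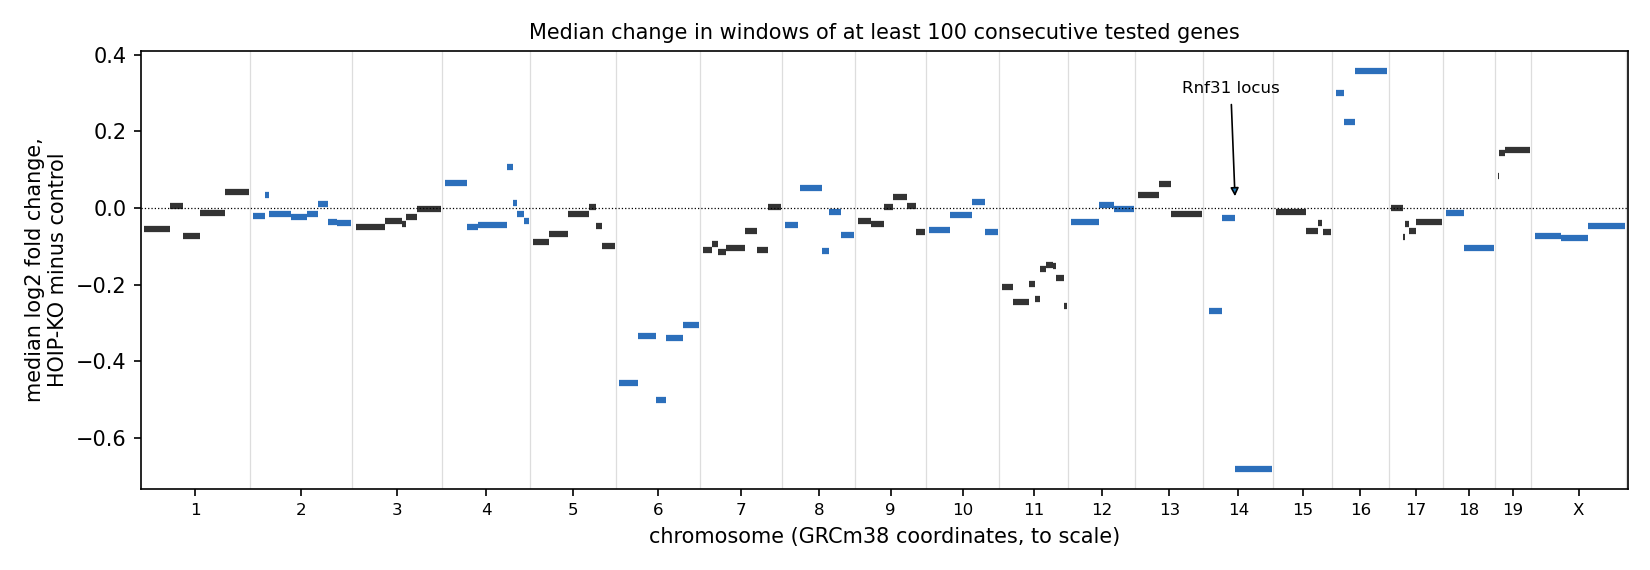
Median log2 fold change of FPKM + 1, HOIP-KO minus control (vertical axis), in windows of at least 100 consecutive tested genes along chromosomes 1 to 19 and X (horizontal axis, GRCm38, to scale). Each bar is a window and colours alternate by chromosome. Bars run from −0.68 in the last window of chromosome 14 to 0.36 on chromosome 16. Rnf31 lies just inside that window of chromosome 14, whose start was set by the count of genes.

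Splicing differences were rarely detected. Of 2790 exon-skipping and 733 intron-retention pairs, limma called 2 and 0 at an adjusted p under 0.05, and 174 and 34 had an unadjusted p under 0.05. Chance alone gives an unadjusted p under 0.05 in a share of 0.05 of the pairs. The 174 lay little above that share and the 34 below it. Both called exons were singled out after their values were seen. Inclusion of a Pawr exon (chromosome 10, 108382730 to 108382861) was 46.5% ± 6.27 in control tumours, and the skipping form was listed at 0 in all HOIP-KO tumours (adjusted p = 0.0365). Inclusion of an Anks1 exon (chromosome 17, 27978427 to 27978489) was 94.9% ± 6.09 in control and 3.57% ± 7.11 in HOIP-KO tumours (adjusted p = 0.00682), at a mean of 3.40 FPKM over both forms. The HOIP-KO SD exceeds its mean, so nearly all of that mean came from a single tumour. In the other HOIP-KO tumours the including form was at or near 0. In the simulation, changes of 20 percentage points were never called and 24.9% of changes of 40 points were. It changed only events with a mean share near the middle of the range. Changes of 20 points at such events were thus not detectable here, and detection at other events was not simulated.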

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

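Libraries were compared within their group for every reported gene that the rule names, every list median and 6 library measures, and 35 of 256 groups held 1 library far from the other 3, where chance gives 12.8 (about 1 in 20). HOIP-KO tumour 2 was that library in 18 of the 35. No technical or biological source of these single-library values was tested, and the test of the events given to no gene was chosen after the result was seen.

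In HOIP-KO tumour 2 the respiratory chain genes Sdhb (346 FPKM against 238 to 249 in the other HOIP-KO tumours), Cox5a (567 against 295 to 338) and Atp5g1 (306 against 198 to 212) stood highest. The oxidative phosphorylation median was 1.12 against 0.618 to 0.641. B2m, of MHC class I, was at 1080 FPKM against 762 to 801, and the MHC class II median at 0.379 against −0.0854 to −0.0738. The globins Hba-a1 (83.1 against 29.6 to 34.0 FPKM) and Hbb-bs (148 against 55.8 to 60.4) were also higher, as was the erythroid median (−0.0408 against −1.41 to −1.32). Muscle Ckm was at 3.86 FPKM against 1.43 to 1.82 and Cd79a at 4.92 against 3.8 to 3.88. Lower in the same tumour were Fn1 (12.9 against 28.7 to 31.6 FPKM), Vwf (13.4 against 20.5 to 21), Sharpin (11.6 against 23.6 to 24.5), Tyrp1 (1870 against 2100 to 2150) and the cholesterol synthesis median (−0.326 against −0.0093 to 0.0259). This library also had the fewest distinct events (83700 against 88200 to 88900) and the highest summed gene FPKM (348000 against 282000 to 293000) of its group.

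Of the other HOIP-KO tumours, tumour 1 stood low for Cxcl16 (3.88 against 4.61 to 4.72 FPKM) and for the type I interferon median (0.192 against 0.478 to 0.502). Tumour 3 was the only HOIP-KO tumour with a Dppa4 value (0.515 FPKM, the others listed at 0). Tumour 4 stood high for the p53 target median (0.0486 against −0.118 to −0.0961), and was the only HOIP-KO tumour with an Acsbg1 value (0.581 FPKM, the others listed at 0).

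Among control tumours, tumour 1 stood high for Gas7 (85.8 against 44.8 to 46.3 FPKM), Postn (11.4 against 8.07 to 8.58), H2-Q4 (2.83 against 1.88 to 2.00), Ctss (20.7 against 17.6) and Acsbg1 (23.9 against 19.7 to 20.2). Its NF-kB median was 0.062 against −0.0191 to −0.01 and its Schwann and nerve median 0.336 against −0.168 to −0.104. Tumour 2 had the highest summed gene FPKM (309000 against 295000 to 297000) and the lowest share of intron-retaining forms (9.55% against 10.4% to 10.5%). B3galt5 was at 1.49 FPKM in tumour 3 and listed at 0 in the others. Tumour 4 stood high for Ccl6 (17.9 against 6.71 to 8.37 FPKM) and Psme2 (28.1 against 19.8 to 20.3).

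Of the events that could be given to no gene, some separated the groups. Of 949 such events with a mean of at least 1 FPKM, 84 were higher in all 4 HOIP-KO tumours than in every control tumour (8.9%, where chance gives 1.43%), and 14 of these were listed in no control tumour. A further 120 (12.6%) were lower in all 4. Tested genes separated in the same way at 13.5% upwards and 17.3% downwards, so these events did not stand out from them.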

How the results depend on the processing

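The alternatives chosen after the results were seen were median-ratio scaling, the 3 single kinds of gene value, genes whose values agreed, and the removal of chromosomes 6, 11, 14, 16 and 19. Rnf31 stayed called lower in each alternative that gave it a value, from −1.84 with a pseudocount of 0.1 to −1.21 without HOIP-KO tumour 4; end-site sums, agreeing genes and the removal of chromosomes, its own among them, gave it none. Apart from the removal of chromosomes, called genes ran from 1998 (end-site sums) to 3408 (without HOIP-KO tumour 2), against 2718. Without the chromosomes 1625 were called and 783 were lower, all 1625 being among the 1742 calls on the remaining chromosomes; fewer genes were tested. Leaving out each library gave 2153 to 3408 called genes, 927 to 1443 higher, 1205 to 1965 lower, 689 to 738 changed 2-fold, 9 to 10 gene lists and 5 chromosomes.

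Camera passed 9 gene lists, or 0 with an estimated correlation, so these calls depend on how correlation between genes is handled. Fry, which tests a list against no change and not against other genes, passed 16. With gene values from end-site sums, Optn (−0.58, adjusted p = 0.287) and Trpm1 (−0.54, adjusted p = 0.486) reversed; the cause was not tested. Of the 105 genes named by the rule, 104 kept direction and call with the smaller pseudocount, 100 with no filter and 102 with median-ratio scaling. With the replicate block 98 did, and leaving out each library in turn kept 92 to 98. Replicate numbers were used as a block although they did not pair the tumours (same-number correlations −0.019 to 0.125), and 2487 genes, 10 lists and 5 chromosomes then passed. The count tests and count scalings that had been planned were not run, as no counts were given. Without counts the depth is unknown, so low values carry an unstated error.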

Other observations

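The lists and genes of the next 3 paragraphs, the tests of mean absolute medians, of copy number, of the oxidative phosphorylation genes outside the shifted chromosomes and of the macrophage markers were chosen after the results were seen.

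The rise of respiratory genes extended to the TCA cycle. Of 21 genes for the cycle and pyruvate entry, 13 rose and 0 fell (median 0.59, camera adjusted p = 7.99e-08; adjusted p = 0.0969 with an estimated correlation). Mpc2, of the pyruvate carrier, rose from 40.2 ± 3.90 to 104 ± 16.8. Ppargc1a, a coactivator of mitochondrial genes, rose from 12.4 ± 3.64 to 47.5 ± 7.04 FPKM, and Esrra, a nuclear receptor that it coactivates, from 22.4 ± 11.2 to 72.9 ± 16.1. Tfrc, the transferrin receptor, rose from 29.4 ± 9.47 to 92.2 ± 5.81 FPKM, while the glucose transporter gene Slc2a3 fell from 48.0 ± 4.25 to 7.69 ± 2.37. Cytosolic ribosomal protein genes went slightly down (1 rose and 6 fell of 53, median −0.23, camera adjusted p = 0.0139; adjusted p = 0.607 with an estimated correlation). Among HOIP-KO tumours most of them stood highest in tumour 2, such as Rps2 (674 FPKM against 365 to 395, and 462 to 522 in control tumours). Others, such as Rpl23 and Rps9, stood lowest there, so the fall was not shared evenly by the HOIP-KO tumours.

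Cartilage matrix genes fell (0 rose and 10 fell of 11, median −2.24, camera adjusted p = 1.99e-08; adjusted p = 0.0249 with an estimated correlation), as did germline and pluripotency genes (0 and 7 of 8, median −2.03, adjusted p = 3.86e-08; adjusted p = 0.00546 with an estimated correlation). Both lists were built around the largest falls, so these p-values are no independent evidence. Col2a1, of type II collagen, fell from 76.3 ± 38.8 to 7.37 ± 1.18 FPKM. Hapln1, a cartilage link protein, was at 9.78, 4.21, 5.53 and 3.48 FPKM in control tumours 1 to 4 and listed at 0 in all HOIP-KO tumours. Sox6, a chondrocyte transcription factor (log2 fold change 0.22 ± 0.22), and the homeobox gene Rhox5 (444 ± 34.4 and 488 ± 132 FPKM) were the members not called.

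Map3k14, which encodes the NF-kB-inducing kinase NIK, rose from 1.34 ± 0.35 to 5.17 ± 0.88 FPKM, and Met, the HGF receptor, from 17.2 ± 2.26 to 69.0 ± 18.7. Irf4, a transcription factor of melanocytes and lymphocytes, fell from 11.4 ± 0.94 to 0.72 ± 0.40 FPKM. The macrophage-expressed genes Fcer1g and Ly86 rose from 5.71 ± 0.57 to 18.2 ± 4.70 and from 2.28 ± 0.05 to 8.37 ± 1.55 FPKM.

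All 35 divisions of the 8 libraries into 4 and 4 were refitted. Only the real one (1 of 35) gave 2718 called genes, 723 changed 2-fold, 1203 higher or 1515 lower, the highest other value being 1 in each case. Standing alone is the most that 35 divisions can show, so chance is made unlikely for these counts but is not excluded. The measures were not adjusted for their number. The real division did not stand alone for the number of gene lists (9, reached by 3 of 35, highest other 9), of chromosomes (5, reached by 11 of 35, highest other 5) or of splicing events (2, reached by 3 of 35, highest other 3). Chance therefore stays open for these numbers. The other divisions that reached the real counts of lists, chromosomes or splicing events exchanged 1 library between the groups and so kept part of the real contrast. The 18 that mixed the groups evenly gave at most 3 lists, 0 chromosomes and 1 splicing event. For the size of the shifts the real division did stand alone: the mean absolute median was 0.33 over the lists (highest other 0.24, 1 of 35) and 0.0985 over the chromosomes (highest other 0.0569, 1 of 35).

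Genes on chromosomes 6, 11 and 14 were lower and those on 16 and 19 higher, Rnf31 and Dct being on chromosome 14. A bias by GC content or transcript length is argued against, since at least 99.3% of each chromosome's shift remained after its trend was removed. At least 67.3% of the genes of chromosomes 6 and 16 lay on the shifted side in each expression tertile and 51.9% or more of those of chromosome 14, but these chromosomes were divided after their shares were seen, so the test lends a copy number difference no support. Along chromosome 14 the share ran from 49.0% ± 5.0 (32.2 to 55.6 Mb) to 81.7% ± 2.9 (from 55.6 Mb). This difference of 32.7 ± 5.8 points argues against a change of the whole chromosome. On chromosome 6 the difference was 16.2 ± 5.3 and on chromosome 16 it was 0.4 ± 5.0. The windows of chromosome 6 thus also differed beyond their error, but its lowest share was 68.8%, so most genes were shifted in each window. Copy number changes of segments, or of chromosomes 6 and 16, stay open, and whether any arose with the knockout, in a clone or by drift was not tested.

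Oxidative phosphorylation genes such as Sdhb and Atp5o rose. After removal of the trend with GC content and length their median was 0.74. Before removal it was 0.71, which 0% of 10000 random lists matched on GC content, length and expression reached (highest 0.46). Those lists were drawn gene by gene and so lack the correlation within this list (estimated at 0.52), which makes 0% look stronger than it is. Outside chromosomes 6, 11, 14, 16 and 19, 16 of the 23 genes had a median of 0.75 (camera adjusted p = 7.43e-09 with the preset correlation; over all chromosomes the list had an adjusted p of 0.324 with an estimated correlation). The medians argue against a GC or length bias and against the chromosome shifts as the whole source. The cell type that carries the rise was not tested.

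Macrophage markers such as C1qa and interferon genes such as Ddx58 rose. A lower share of tumour cells would raise every host marker, yet the macrophage markers exceeded 38 other host markers by 1.19 ± 0.21 (log2; means 0.81 and −0.38). That argues against such a shift only if the other markers came from host cells alone, which was not tested. Whole-tumour RNA does not show their source, and Fn1, among them, fell from 171 to 25.6 FPKM. Genes within the lists also moved together (estimated correlation 0.34 for fibroblast and 0.81 for erythroid genes), so the error may be understated. A lower share of tumour cells therefore stays open, as do more macrophages or more expression in each. Whether macrophages are the source of the interferon rise cannot be told apart from a response in other cells: the 28 tested interferon genes differed from the markers by −0.47 ± 0.19 (medians 0.45 and 0.92), a test first run on the called genes alone; only a larger rise than that of the markers would have argued against macrophages.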
